A study of Mus musculus with 3 samples.

How the data were processed

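RNA from the genital tubercle of 3 mouse embryos labelled male, at embryonic day 14 and Theiler stage 22, was measured on 1 array per embryo. Per the labels' protocols, females of the FVB/N strain were mated to males carrying an Acta2 reporter transgene with a yellow fluorescent protein, the tubercle was dissected by its fluorescence, and total RNA was purified with a Qiagen RNeasy kit. Per the labels it was amplified in 2 rounds with aminoallyl nucleotides and coupled to biotin. Where amplification starts at the 3′ ends of transcripts, probe sets far from that end can read low in a sample whose RNA was shorter. The samples form 1 group and differ in 1 label, the landmark, which is visible fingers in replicate 3 and indented footplate borders in replicates 1 and 2. Nothing in the labels says that the embryos shared a litter or a batch, and the differences between samples mix animals, dissection, amplification and hybridisation.

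The deposited table holds 1 linear intensity per probe set and sample, from the authors' scanner software, GCOS, per the submitters' processing notes. Its version, the algorithm and its settings are not given in the sources used here. Deposited intensities ran from 0.13 to 96445, and the mean after trimming 2% of values at each end was 1500.0 in every sample, so a global scaling had been applied before deposit. The median signal was 205, 334 and 272 in replicates 1, 2 and 3. No scanner files were used, so background correction and probe summary could not be redone. Every column of the table was matched to a sample, with 0 columns left over.

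Of 45101 probe sets, 64 controls were set aside and 45037 analysed. A platform annotation gave exactly 1 gene symbol to 34945, several to 932 and none to 9160, and only those with 1 symbol were named. Symbols were updated through Entrez identifiers in the RefSeq table of assembly GRCm38.p6, where 34741 matched and 0 changed. Each gene was represented by its probe set with the highest mean signal. Of 9010 genes with several probe sets, 4351 had some but not all of them above background in 3 of 3 samples, so a gene called below background refers to that 1 probe set. Among the lists fixed in advance this mattered for 2 genes, Sox5 and Xist, which had some probe set above background in each of the 3 samples. Listed genes without a symbol in that annotation were not analysed here. No genome build is named for the arrays and no coordinates are given.

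Background in each sample was the 95th percentile of 81 probe sets of olfactory, vomeronasal and bitter taste receptors, genes of sensory epithelia. Signals below 1 were set to 1 and log2 transformed. Samples were to be aligned if their medians differed by more than 0.1 on the log2 scale. They differed by 0.23 over probe sets above background in 3 of 3 samples and by 0.70 over all probe sets, and were aligned on the former, a reading of the rule made after the data were seen. Signals are printed as deposited, while differences, folds and SDs of log2 values are after alignment. Where a gene was not above background in 1 of 2 samples compared, the fold is a lower bound, taken against the background of that sample or its own signal if higher, and is written as at least so many fold.

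The landmark contrast set replicate 3 against replicates 1 and 2 in limma with lmFit and eBayes, two-sided with Benjamini-Hochberg adjustment, over 29065 probe sets above background in at least 1 sample. It leaves 1 residual degree of freedom and assumes that the lone sample varies like the others. The same fit was run with each other sample alone. It was tested on simulated data with 60 probe sets changed by 2-fold, 70 by 8-fold and 70 by 64-fold. None of them passed the adjusted threshold, although unadjusted p fell under 0.05 for 15, 67 and 69, and the median estimated log2 differences were 0.98, 3.17 and 5.89. There were 0 false calls, which says nothing about error control where nothing was called.

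Gene lists covered hedgehog, steroid hormone and retinoic acid signalling, Fgf, Bmp and Wnt signalling, posterior Hox, tubercle mesenchyme transcription factors, proliferation, extracellular matrix, hypoxia and glycolysis, immediate early and stress genes, oxidative phosphorylation and ribosomal proteins. Cell type lists covered smooth muscle, epithelium, differentiated epidermis, skeletal muscle, cartilage and bone, endothelium, erythroid cells, macrophage, nerve and glia, gonad, kidney and bladder, hindgut, brain and spinal cord and liver, and the sex lists were Y-linked and X inactivation. For each list except the sex lists, the median log2 difference of 1 sample from the mean of the other samples was placed among 10000 random lists of the same size drawn from 20 bins of mean level. A list was called when it lay beyond the outer 0.1% at either end. In simulated data with noise drawn independently for each gene, a list of 12 genes shifted by 1 on the log2 scale was found at 1.14 and percentile 100. There 0 of 100 unshifted lists were called.

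Genes were named by rule. For levels these were the 4 detected members of each list with the highest mean signal, members not above background in 3 of 3 samples where these numbered 5 or fewer, and a fixed set of tubercle, cell type and sex genes. For differences they were the 10 highest and 10 lowest genes per lone sample, among genes with a mean above the median of detected genes, whose lone value lay outside the other samples by more than 3 times the distance between those. The lists, the naming rule, the tests and most alternatives were fixed before the data were examined. Alternatives were other backgrounds (the 99th percentile, or bacterial control probe sets), a count of at least 2 of 3 samples, quantile normalization, an offset of 50 before log2, no filter or a filter of 3 of 3 samples, a variance trend, averaging the probe sets of a gene, probe sets with a plain name ending, and leaving out each sample in turn. For list shifts signals below the highest aligned background of the 3 samples were also set to it, so that differences became bounds, a choice made after seeing the data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.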

Results

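Gene expression was measured in the genital tubercle, the embryonic outgrowth that forms the penis or the clitoris, of 3 mouse embryos labelled male at embryonic day 14 (Theiler stage 22). The labels place all 3 samples in 1 group and state that none was pooled, so no treatment or control enters the comparisons. The region was dissected under guidance of a fluorescent reporter transgene named for Acta2 (smooth muscle actin). Each sample was hybridised to 1 array of 45101 probe sets. Background was set at 135.8, 253.1 and 197 signal units in replicates 1, 2 and 3, and 25776, 24802 and 25248 probe sets lay above it. In 3 of 3 samples 21612 probe sets, or 48.0% of the 45037 that are not controls, were above background. By gene, 11006 of 18193 genes measured (60.5%) were above background in 3 of 3 samples. Levels below are deposited signals, as mean ± SD with n = 3, and the small number of arrays limits the precision of every value.

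The sex label was checked first. Xist, the non-coding RNA that coats the inactive X chromosome of female cells, had a signal of 61883 in replicate 3 on its main probe set, which was not above background in replicates 1 and 2, where it read 8.05 and 118. After alignment of the samples this was at least 429-fold over replicate 1 and at least 269-fold over replicate 2. The Y-linked translation factor gene Eif2s3y had signals of 4384 and 3738 in replicates 1 and 2, and read 37.9, not above background, in replicate 3. The Y-linked histone demethylase genes Kdm5d (529, 441 and 37.1 in replicates 1, 2 and 3) and Uty (616, 494 and 45.3) followed the same order against background. Thus 3 of 3 Y-linked genes measured were above background in replicates 1 and 2 and 0 of 3 in replicate 3. Probe sets of these genes were not uniform, since 1 of the 3 Xist probe sets was above background in every sample, at 293, 286 and 58683. Among further Y-linked probe sets, those of Eif2s3y and Kdm5d included some above background in no sample, and those of Kdm5d and Uty some above it in replicate 2 alone. Every Y-linked probe set read below background in replicate 3. All 3 samples carry the male label, and these values go against it for replicate 3. That sample is called the library of doubtful sex label below, and every direction drawn from it carries that limit.

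**Figure D1:**
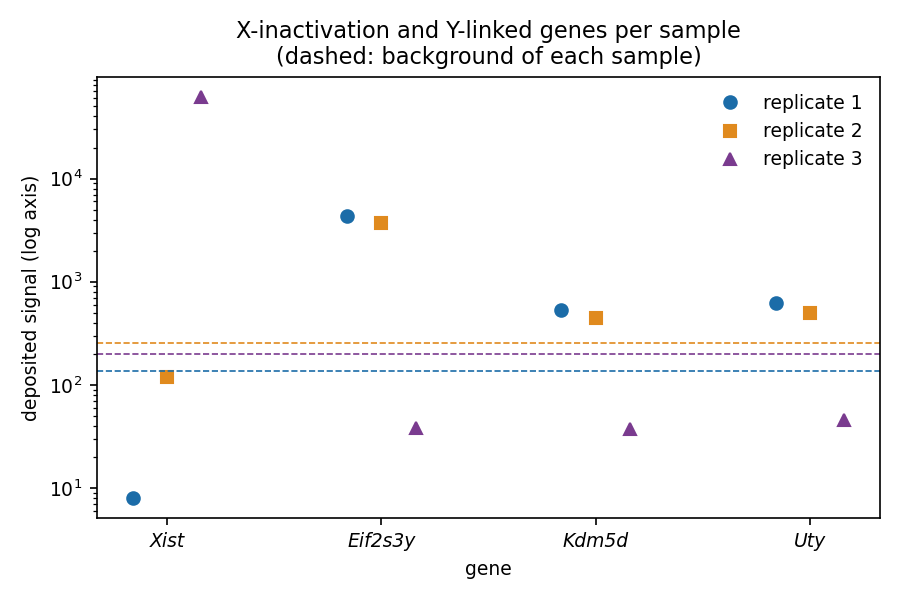
Deposited signal (log axis) of the main probe sets of Xist and of the Y-linked genes Eif2s3y, Kdm5d and Uty in each of the 3 samples, 1 point per sample, with the background of each sample as a dashed line. Xist stands at 61883 in replicate 3 and below background in replicates 1 and 2, and the Y-linked genes lie above background in replicates 1 and 2 alone.

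Hedgehog signalling, which drives outgrowth of the tubercle from its urethral epithelium, was represented in full, with 12 of 12 measured genes above background in 3 of 3 samples. The ligand Shh had a signal of 13844 ± 2186, its receptor Ptch1 34527 ± 6797 and the transcription factor Gli1, a direct target of the pathway, 750.2 ± 213 (SD, n = 3). The transcription factors Gli3 and Gli2 read 18226 ± 674 and 14334 ± 1243, and the co-receptor Gas1 17732 ± 4743. Of the posterior Hox genes, which pattern the caudal end of the trunk, 7 of 10 were above background in 3 of 3 samples. Hoxd13, which together with Hoxa13 is required for tubercle formation, had 40748 ± 2303, Hoxa9 26665 ± 1998, Hoxd10 7809 ± 889.7 and Hoxa10 4829 ± 1026. The probe set of Hoxa13 read 146, 250.4 and 170.1 in replicates 1, 2 and 3 and was above background in replicate 1 alone. Hoxd11 was above background in 2 samples and Hoxd12 in 1.

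Of the Fgf, Bmp and Wnt signalling list 18 of 22 genes were above background in 3 of 3 samples. Ctnnb1, which encodes β-catenin, had 73222 ± 7748, the ligand Wnt5a 40345 ± 3647, the secreted Wnt inhibitor Sfrp2 31263 ± 8805, the ephrin Efnb2 19542 ± 3989.9 and the ligand Bmp4 9133 ± 3588. Fgf8, a ligand of the distal urethral epithelium, was not above background in any sample (9.12, 12.4 and 9.64), nor was the Bmp antagonist Nog. Fgf10 read 226, 248 and 250.4 and was above background in replicates 1 and 3, as was Wnt3. Among the transcription factors of tubercle mesenchyme 16 of 18 were above background in 3 of 3 samples. Isl1 had 48464 ± 4187, Prrx1 29528 ± 3544, Tbx3 16151 ± 3616, Twist1 13249 ± 4461 and Tbx4 7222 ± 1232. Osr1 (132, 1387 and 526) and Dlx6 (62.4, 433 and 59.5) were above background in 2 samples and 1 sample.

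Steroid hormone signalling had 6 of 8 measured genes above background in 3 of 3 samples. The oestrogen receptor gene Esr1 had 2985 ± 738, the receptor co-chaperones Fkbp4 and Fkbp5 4813 ± 629 and 4091 ± 942, and the coactivator Ncoa1 2326 ± 183. Esr2 and Hsd17b3, an enzyme of testosterone synthesis in the testis, were not above background in any sample. Of the retinoic acid signalling list 9 of 10 genes were above background in 3 of 3 samples, with Cyp26b1, which degrades retinoic acid, at 13587 ± 3149, the binding proteins Crabp2 and Crabp1 at 5083 ± 2729 and 2512 ± 687, and the receptor Rarb at 2345 ± 1389. Stra6 was above background in replicates 1 and 3.

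Smooth muscle genes were partly represented, with 7 of 12 above background in 3 of 3 samples. Acta2, for which the reporter used in dissection is named, had 3462 ± 1578, Synpo2 10659 ± 835, Tpm2 8411 ± 1402 and the kinase Mylk 5383 ± 1105. Of the other genes of this list, Cnn1 and Lmod1 were above background in no sample. Actg2, Tagln and Myocd were above it in replicate 1 alone, the sample with the lowest background. The signal of Myocd was highest in replicate 2 (139, 186 and 106 in replicates 1, 2 and 3). Epithelial genes had 16 of 17 above background in 3 of 3 samples. Trp63, the transcription factor of stratified epithelia, had 20517 ± 2627, Perp 19349 ± 2632, the basal keratin Krt14 17251 ± 4646, Epcam 15995 ± 1357 and E-cadherin (Cdh1) 5611 ± 762. Cldn4 was above background in 2 samples. Of genes of differentiated epidermis 7 of 10 were above background in 3 of 3 samples, among them Krt6a (6006 ± 3215), the suprabasal keratin Krt10 (5518 ± 1175), the cornified envelope gene Lor (2742 ± 1018) and Sbsn (1813 ± 489). Flg and Ivl, which mark later cornification, were above background in no sample and Sprr1a in 2.

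Genes of general cell programmes were mostly above background. All 16 of 16 measured proliferation genes were above background in 3 of 3 samples, with the replication licensing factors Mcm7 and Mcm4 at 39139.8 ± 2724 and 25520.5 ± 3251, the topoisomerase Top2a at 38987 ± 4885 and Mki67 at 27435 ± 1336. The same held for 14 of 14 extracellular matrix genes, among them the collagens Col3a1 (62804 ± 3772) and Col1a2 (39979 ± 4218), Vcan (50210.0 ± 4989) and Fbn2 (39961 ± 10594). It held too for 12 of 12 oxidative phosphorylation genes, with Atp5a1 at 45690.5 ± 1085, Atp5b at 29393 ± 4267, Cox5a at 28003 ± 3563 and Cox4i1 at 24424 ± 4039.8. Ribosomal protein genes had 10 of 11 above background, with Rps20 at 67611 ± 7600.3, Rpl7 at 66415 ± 7252, Rps2 at 61669.5 ± 4417 and Rps3 at 59438 ± 1166, and the probe set of Rps16 above background in no sample. Hypoxia and glycolysis genes had 10 of 12, with Pgk1 at 51502 ± 4756, Ldha at 18193 ± 675, Bnip3 at 15311 ± 3866 and Aldoa at 10692 ± 2882, while Adm and Car9 were above background in 2 samples each. Immediate early and stress genes had 9 of 12, with Ier2 at 5642 ± 1737, Hspa1b at 4389 ± 1391, Egr1 at 2874 ± 373 and Jun at 2317 ± 226. Fosb and Junb were above background in no sample and Atf3 in 2.

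Markers of other cell types were above background to very different extents. Endothelial genes had 9 of 11 above background in 3 of 3 samples, among them the transcription factors Erg (2683 ± 689) and Sox17 (2669 ± 492), the receptor Kdr (2205 ± 976) and Esam (2058 ± 334), whereas Pecam1 (217, 147 and 133) and Tie1 were above background in replicate 1 alone. Nerve and glia had 7 of 12, among them the glial receptor Erbb3 (7155 ± 2287), the neurofilament Nefl (941 ± 219.6), Elavl4 (576 ± 125) and Stmn2 (468 ± 210.4). The Schwann cell regulator Sox10 (155, 228 and 266) was above background in replicates 1 and 3, as was Nefm. Fabp7 was above it in replicates 1 and 2, Foxd3 in replicate 1 alone and Elavl3 in replicate 3 alone. Macrophage genes had 3 of 12, namely Csf1r (2276 ± 756), Mrc1 (1235 ± 398) and Lyz2 (580.4 ± 283). Cartilage and bone had 4 of 12, namely Sox6 (1222 ± 440.1), Sox9 (802 ± 302), Sp7 (551 ± 108) and Alpl (399.7 ± 73.9). Kidney and bladder had 4 of 9, namely Upk1b (2213 ± 1147), Wnt11 (1025 ± 236), Ret (730.4 ± 120.1) and Upk2 (556 ± 114), and gonad 1 of 9, namely Star (349 ± 88.5). Upk1a was above background in replicates 1 and 2, and Pax8, Wt1, Cdh16 and Upk3a in no sample. Hindgut had 0 of 7 and brain and spinal cord 0 of 7. The lists of liver (3 of 7), erythroid (6 of 8) and skeletal muscle genes (5 of 15) differed between samples and are described with the list shifts. Over all lists, 211 of 305 measured genes were above background in 3 of 3 samples. Without replicate 3, the library of doubtful sex label, 221 were above background in both remaining samples. Of the 81 sensory receptor probe sets that define background 5% pass in each sample by construction, and 1 passed in 3 of 3.

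**Figure D2:**
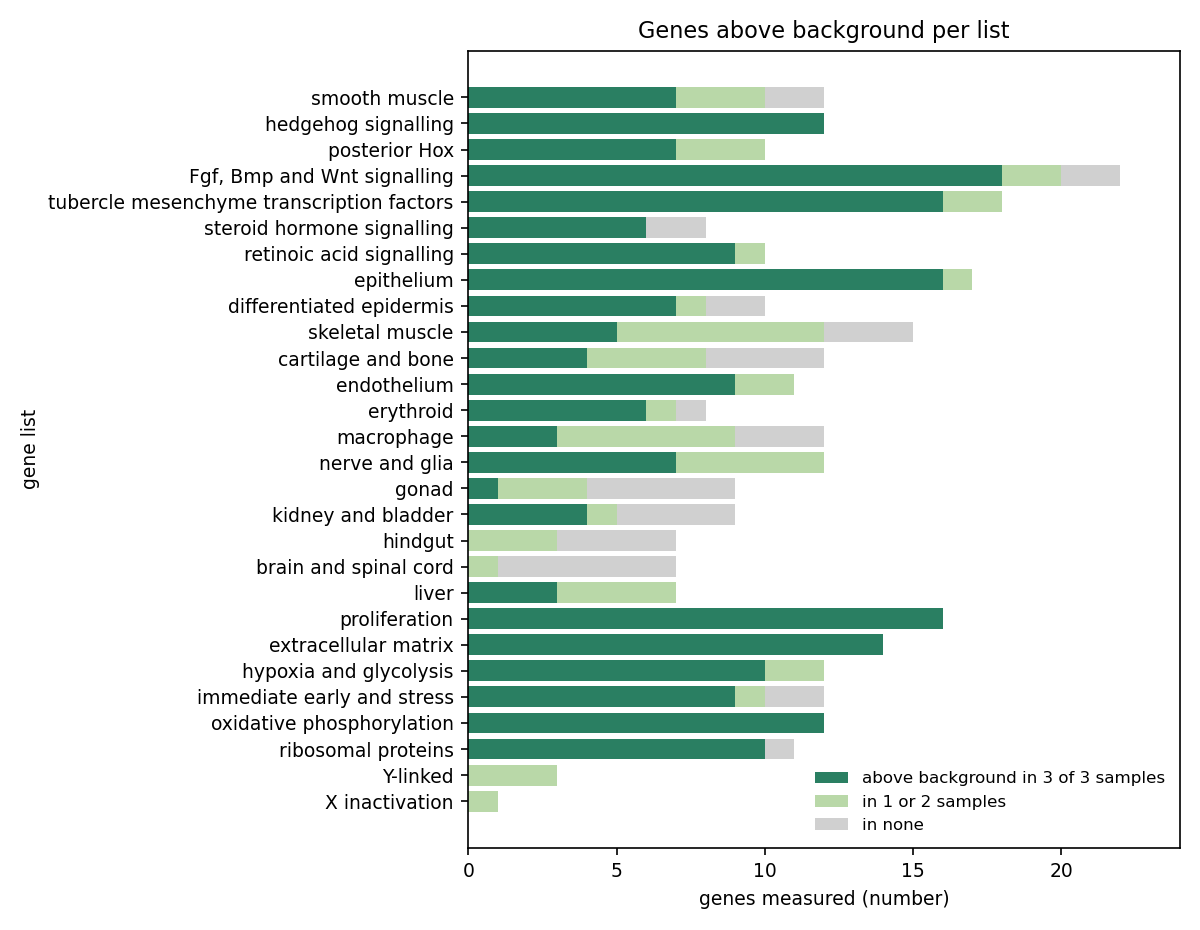
Number of measured genes in each list (x axis), split into those above background in 3 of 3 samples, in 1 or 2 samples, and in none, with 1 bar per list. Proliferation (16 of 16), extracellular matrix (14 of 14) and hedgehog signalling (12 of 12) are complete, while hindgut (0 of 7) and brain and spinal cord (0 of 7) have no gene above background throughout.

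The 3 samples were set against each other across the 21612 probe sets above background in 3 of 3, which are not independent replicates. Of 53 genes of the hedgehog, posterior Hox, Fgf, Bmp and Wnt and tubercle mesenchyme lists above background in 3 of 3 samples, 35 had an SD on the aligned log2 scale below the median of all these probe sets, with a range from 0.02 (Wnt5a) to 1.43 (Osr2, chosen after its values were seen). Shh had an SD of 0.12, Hoxd13 of 0.14, Gas1 of 0.53 and Bmp4 of 0.66, all with n = 3. Acta2 varied more (SD 0.70), with signals of 5273, 2736 and 2378 in replicates 1, 2 and 3. The median SD over probe sets was 0.364 on the log2 scale, and 0.42, 0.37 and 0.32 in the tertiles of low, middle and high level. The 53 list genes had a median SD of 0.298, near that of the high tertile. They were not matched in level, so they are not shown to vary less than other bright genes. Pearson's r across probe sets was 0.903 between replicates 1 and 2, 0.936 between 1 and 3 and 0.944 between 2 and 3, with Spearman's rho of 0.881, 0.921 and 0.930. Over 2-fold differences were found in 4363 probe sets (20.2%) between replicates 1 and 2, 2971 (13.7%) between 1 and 3 and 2128 (9.85%) between 2 and 3. At most 10 probe sets held the same value in any pair of samples, so each sample was counted as its own library.

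The landmark is the 1 label that differs between samples, with visible fingers in replicate 3 and indented footplate borders in replicates 1 and 2. Among the better expressed genes whose value in replicate 3 stood clear of both others, the T-box transcription factor Tbx18 was higher by 1.73 ± 0.60 (log2 difference ± SE), with signals of 1134, 1431 and 4142 in replicates 1, 2 and 3. These SEs and those of the other lone samples are from limma, which pools variance across probe sets. The naming rule also favours genes with close values in the other samples, so the SEs are not each gene's own replicate error. The bHLH transcription factor Sim1 was higher by 1.71 ± 0.60 and the retinoic acid receptor Rarb by 1.38 ± 0.60. Appl1 (2.11), Hook3 (1.91), Gigyf2 (1.68), AW551984 (1.63), Vamp7 (1.42), Tbc1d15 (1.36) and Plcxd2 (1.25) had the other positive differences. The fetal serum protein gene Afp was lower, at -2.67 ± 0.65, as were the vascular ligand Angpt1 (-1.28), the collagen Col13a1 (-1.26) and the chromatin remodeller Smarcb1 (-1.39). Exph5 (-2.25), Irak1 (-1.58), Pfdn5 (-1.36), Csnk2a2 (-1.29), Niban1 (-1.26) and Coq9 (-1.23) completed the 10 lowest. By this rule 222 of 6663 genes were higher and 328 lower, 47 of them over 2-fold. How many genes meet this rule by chance was not estimated for this or any other sample, so these counts are no measure of a difference. None of the probe sets fitted was called by limma at a Benjamini-Hochberg adjusted p under 0.05. With the fit limited to probe sets above background in 3 of 3 samples limma called 1 probe set, of Xist (adjusted p = 0.0180), and with alignment on the median of all probe sets, chosen after seeing the data, it called 86. In simulated data of this design 0 of 70 probe sets changed by 64-fold reached the threshold, so the contrast had no power at the sizes simulated. It also cannot separate the landmark from sex or any other feature of replicate 3, the library of doubtful sex label.

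The same fit and the same rule for naming genes were applied to each other sample alone, each against the mean of the remaining samples. Those always included replicate 3, the library of doubtful sex label. In replicate 1 the embryonic myosin Myh3 was higher by 3.76 ± 0.54 (log2 difference ± SE), the platelet chemokines Ppbp and Pf4 by 3.03 ± 0.58 and 1.48 ± 0.49, and Tal1, a transcription factor of blood formation, by 2.56 ± 0.48. Tgm2 (2.39), Htr3a (1.70), Cdr2 (1.52), Marchf3 (1.52), Rsad2 (1.51) and Creg1 (1.47) were next. The kinase Gsk3b was lower at -3.10 ± 0.55, the RNA-binding protein gene Igf2bp1 at -2.94 ± 0.53 and the laminin Lamc1 at -2.56 ± 0.47. Mia3 (-2.31), Rgmb (-2.12), Kansl1 (-2.05), Thoc2l (-1.93), Sbno1 (-1.92), 4632427E13Rik (-1.65) and Tbc1d23 (-1.63) followed. Replicate 1 also stood apart in control probe sets that bear on RNA quality, with 18S at a median log2 difference of -2.13. No test separated this from the differences of single genes there. In replicate 2 the largest positive differences among genes that met that rule were in Birc6 (2.19 ± 0.46), the transcription factor Runx1 (1.91 ± 0.52), Chd8 (1.70), Bzw2 (1.43), the histone demethylase Kdm5b (1.38), 3110021A11Rik (1.28), Ggps1 (1.26), Cd44 (1.23), Ubl3 (1.17) and Cxcl14 (0.99). The negative ones there were in Otud4 (-3.66 ± 0.59), Mycbp (-2.07), Gprin2 (-2.05), the endothelial and progenitor marker Cd34 (-1.96), Cenpo (-1.95), Polh (-1.92), Tial1 (-1.74), Nkrf (-1.72), Pithd1 (-1.66) and Ndufaf4 (-1.61). Genes that met the rule numbered 929 higher and 163 lower for replicate 1, 82 of them over 2-fold, and 149 higher and 1202 lower for replicate 2, 172 of them over 2-fold. Bright genes as a whole leaned the same ways. Medians of random lists matched in level to the proliferation genes had limits of 0.01 and 0.54 in replicate 1 and of -0.66 and 0.002 in replicate 2. The balance of these counts may therefore follow a difference shared by bright genes, which was not tested. In these fits limma called none of the probe sets. For replicate 1 the count became 511 (57 higher, 454 lower) among probe sets above background in 3 of 3 samples, 557 (73 higher, 484 lower) with a variance trend, and 144 (34 higher, 110 lower) with alignment on the median of all probe sets. For replicate 2 that alignment, chosen after seeing the data, gave 251.

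Liver genes had the largest differences between samples of the 25 lists compared. In replicate 1, 7 of 7 were higher than the mean of the other samples, with a median log2 difference of 3.74 (percentile 100 among random lists of like level). In replicate 3, the library of doubtful sex label, 0 of 7 were higher, at -3.57. Against replicate 2 alone these medians were 2.64 and -2.55, and with signals below background set to background, chosen after seeing the data, 3.70 and -2.28, with both calls kept. Albumin (Alb) had signals of 42766, 9061 and 1399.9 in replicates 1, 2 and 3, which was 32.5-fold between replicates 1 and 3 after alignment, and alpha-fetoprotein (Afp) had 52165, 40064 and 7049 (7.86-fold). The transthyretin gene Ttr was 30.1-fold and the apolipoprotein gene Apoa1 at least 19.2-fold higher in replicate 1 than in replicate 3, and the fibrinogen genes Fgb and Fga at least 15.1-fold and at least 2.61-fold. The plasma protein gene Ahsg was at least 7.14-fold higher. Against replicate 2, Alb was 5.52-fold and Afp 1.52-fold higher in replicate 1. Replicate 1 also stood apart in control probe sets that bear on RNA quality, with 18S at a median log2 difference of -2.13 and a ratio of 3′ to 5′ signal for Actb of 7.38 against 2.21 and 4.42, and no test separated this from the list shifts of that sample.

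Skeletal muscle genes were higher in replicate 1 in 11 of 12 cases, by a median of 2.21. They were lower in replicate 3, the library of doubtful sex label, in 11 of 12, at -2.20. The embryonic myosin Myh3 was 17.0-fold higher in replicate 1 than in replicate 3, the actins Actc1 and Acta1 9.42-fold and 5.27-fold, the troponin Tnnt1 4.65-fold and the myogenic regulator Myog 3.94-fold. The median for replicate 1 was 1.41 against replicate 2 alone, and that for replicate 3 was -1.31 against replicate 2 alone. With signals below background set to background they were 1.66 and -1.31, with both calls kept. Erythroid genes were higher in replicate 1 in 5 of 7 cases, by a median of 1.02, and lower in replicate 3 in 6 of 7, at -1.09. The red cell anion exchanger Slc4a1 had signals of 18738, 6337 and 1686 in replicates 1, 2 and 3, the haem synthesis enzyme Alas2 2421, 1999.9 and 787 and the transferrin receptor Tfrc 15047, 9014 and 7646. The embryonic globin Hbb-y did not follow, at 59853, 86889 and 77722. Epb42 was above background in replicate 1 alone (603) and Hba-a1 in no sample. The erythroid call in replicate 1 was lost at a median of 0.50 without replicate 3, and at 0.75 under quantile normalization and 0.60 with all probe sets of a gene averaged.

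Of the hindgut list, 3 genes could be compared, and in replicate 3, the library of doubtful sex label, none of them was above background. Their median of -3.39 there therefore rests on signals below background, and with those set to background it was -1.20 and no longer beyond the limits. They were Hnf4a (787, 486 and 57.9 in replicates 1, 2 and 3), Fabp1 (1001, 288 and 172) and Cdh17 (above background in replicate 1 alone, at 160.0), of which Hnf4a and Fabp1 are also expressed by liver cells, and these 3 were named after their values were seen. That call was also lost at -1.74 with an offset of 50, at -1.93 with all probe sets of a gene averaged and at -3.85 without replicate 2. In replicate 2 tubercle mesenchyme transcription factors stood at 0.22 with 10 of 18 genes higher, and ribosomal proteins at 0.08 with 6 of 10 higher, both beyond the upper 0.1% of random lists, whose medians were mostly below 0. Osr1, Osr2 and Dlx6 were among the former, Osr2 with signals of 229.8, 1961 and 701. The ribosomal call was lost at 0.0732 under quantile normalization and 0.12 with all probe sets of a gene averaged. Without replicate 3 both medians lay just below 0 after alignment, at -0.00833 for the transcription factors and -0.000117 for ribosomal proteins. Their sign depends on the alignment, and their positions among random lists were not recorded there. The calls were 9 of 75 comparisons of 25 lists in 3 samples, where 0.15 were expected for genes that vary independently. Genes of 1 list can move together, and the 3 comparisons of a list share the same values, so that number is no measure of chance here. The percentiles describe these 3 samples without a p-value.

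The other lists stayed inside the limits of random lists in every sample. The medians for replicates 1, 2 and 3 were 0.29, -0.33 and 0.03 for hedgehog signalling and -0.06, -0.17 and 0.15 for posterior Hox. In the same order they were 0.15, -0.03 and -0.08 for Fgf, Bmp and Wnt signalling, 0.24, -0.13 and -0.12 for steroid hormone signalling, and 0.15, 0.07 and -0.16 for retinoic acid signalling. Smooth muscle had 0.24, 0.01 and -0.60, epithelium 0.48, -0.13 and -0.30, and differentiated epidermis 0.81, -0.22 and -0.49. Endothelium had 0.20, -0.34 and 0.30, macrophage 0.89, -0.64 and -0.15, nerve and glia -0.13, 0.13 and -0.02, and cartilage and bone 0.18, -0.10 and -0.23. Kidney and bladder had -0.28, 0.03 and 0.12, and gonad 0.63, -0.46 and -0.30. Proliferation had 0.40, -0.42 and 0.06, extracellular matrix 0.09, -0.21 and 0.21, and oxidative phosphorylation 0.17, -0.13 and -0.17. Hypoxia and glycolysis had 0.42, -0.18 and -0.11, and immediate early and stress genes 0.65, -0.36 and -0.22. The nearest to the limits were differentiated epidermis and macrophage in replicate 1 (both at percentile 99.7), then epithelium (0.300) and smooth muscle (0.400) in replicate 3, the library of doubtful sex label. Brain and spinal cord had too few genes above background for this comparison.

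**Figure D3:**
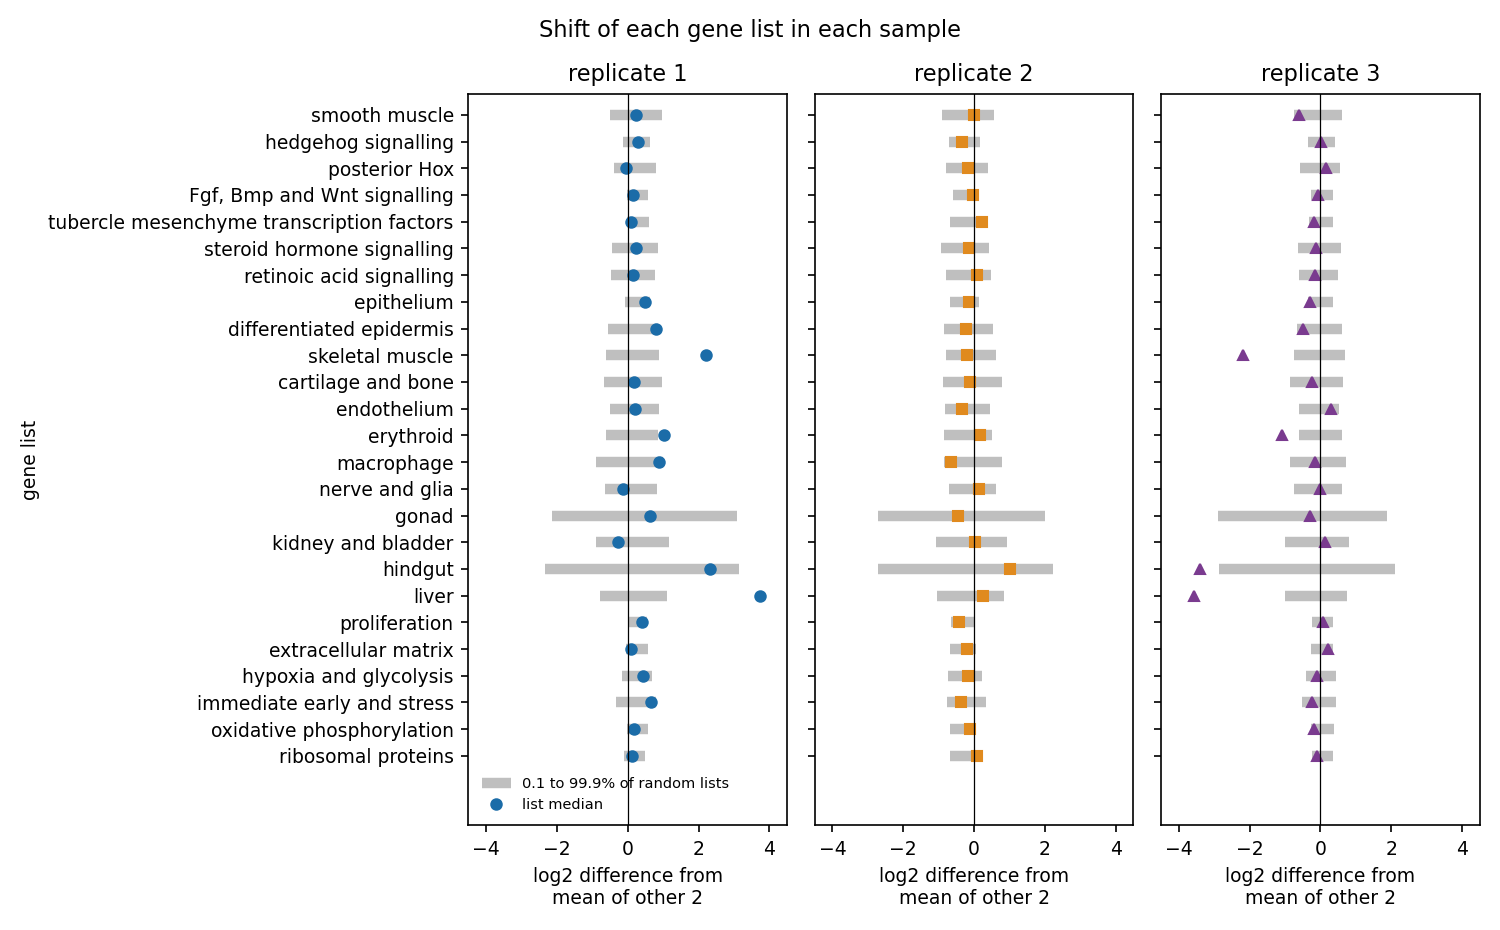
Median log2 difference of each list in each sample from the mean of the other 2 samples (x axis), 1 panel per sample, with grey bars for the middle range of 10000 random lists of the same size and level. Liver lies at 3.74 in replicate 1 and -3.57 in replicate 3, and skeletal muscle at 2.21 and -2.20, all outside their bars.

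**Figure D4:**
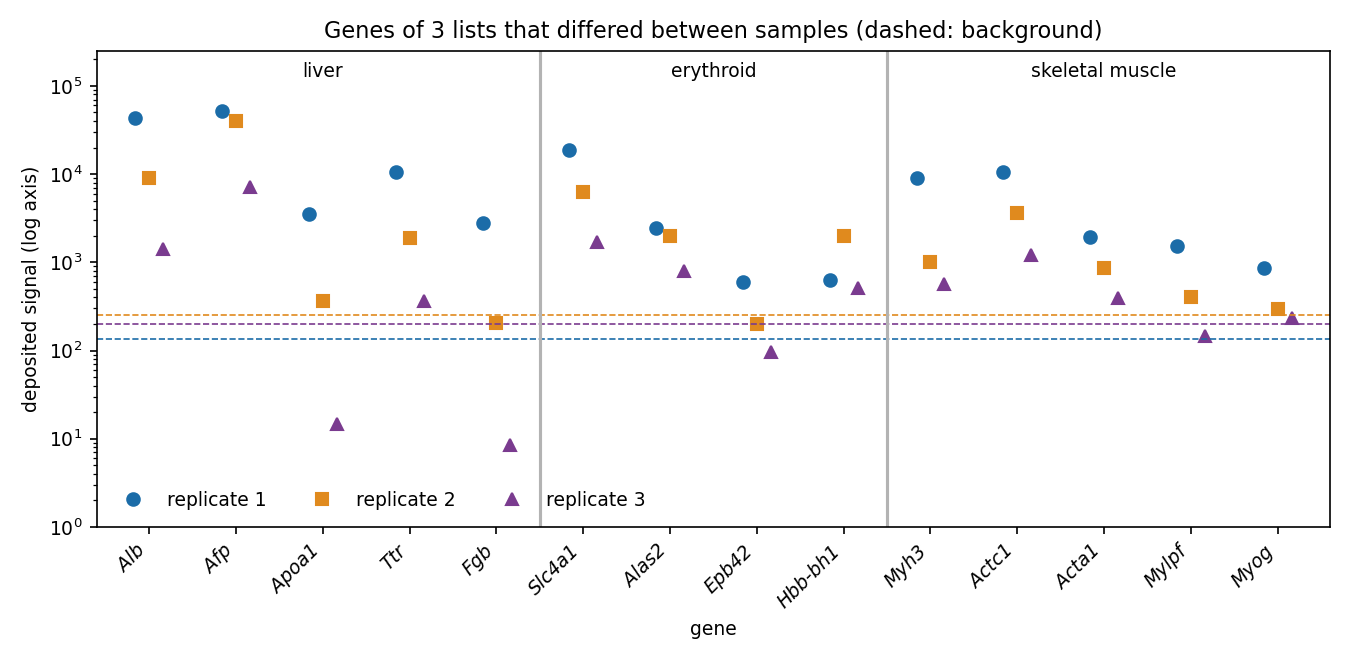
Deposited signal (log axis) of 14 genes from the liver, erythroid and skeletal muscle lists, 1 point per sample, with the background of each sample as a dashed line. Alb stands at 42766, 9061 and 1399.9 and Myh3 at 9136, 997 and 569.7 in replicates 1, 2 and 3.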

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

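Among the tests in this part, that of the array's signal scale was chosen only after the result was seen. Single outlying samples were not screened for in a group of 3, and the results here are signals of control probe sets and of probe sets without a gene symbol. The latter also entered the counts, spreads and fits, and the 18S and Actb controls were cited with the liver genes. The control probe set at the 3′ end of 18S ribosomal RNA had signals of 13587, 78759 and 60294 in replicates 1, 2 and 3, far above background in each. A control probe set of the B1 repeat, a short interspersed element found in many transcripts, had 5515, 9510.0 and 7180.4. A further 2378 probe sets without a gene symbol in the annotation used were above background in 3 of 3 samples.

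The 3 probe sets of 18S were lower in replicate 1 than in the mean of the other samples by a median log2 difference of -2.13, and the ratio of 3′ to 5′ signal was highest there for Actb (7.38, 2.21 and 4.42 in replicates 1, 2 and 3) and Gapdh (21.5, 14.9 and 14.1). With bounds where the 5′ signal was not above background, Pcx (at least 6.48, 2.61 and at least 3.64) left replicates 1 and 3 unordered. Tfrc (4.36, at least 4.705 and at least 3.127) and 18S itself (1.22, 1.12 and 1.44) were not highest in replicate 1, so the ratios did not all point the same way. A lower signal scale of the array is argued against, since 18 probe sets of spikes added after amplification differed by a median of -0.21 (range -0.36 to -0.12). Shorter amplified RNA in replicate 1 stays open. The dimmer probe sets of a gene, against probe sets of the same level that are the brightest of their gene, stood at a median log2 difference of -0.34 there. That met the prediction written before the test, of which the control ratios were no part. It is a value from 1 library against 2 that holds no estimate of variation between samples. No biological explanation was tested, and probe sets of genes listed as low in replicate 1 were not placed along their transcripts.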

How the results depend on the processing

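Alignment on the median of all probe sets, deposited values for list shifts and spread, signals below background set to background, and the spread without the genes of the moved lists were chosen after seeing the data. Mean signals of 146 named genes moved by less than their SD under quantile normalization, 336 of 360 differences of named genes moved by less than the median SD and none turned, and 24 moved further, 20 of them for replicate 1 under that alignment. Counts of probe sets above background ran from 19820 to 28918, with quantile normalization unable to move them since it keeps ranks, the median SD from 0.271 to 0.537, and list genes above background from 175 to 227. The lowest correlation was 0.903 to 0.944 with each replicate left out. The landmark contrast gave 1 call with a filter of 3 of 3 samples and 86 with alignment on all probe sets. For replicate 1 alone the counts were 511 with that filter, 557 with a variance trend and 144 with that alignment, and for replicate 2 alone 251. That alignment adds a constant to the difference between the 2 samples fitted together of every probe set, which enters the residual variance by construction, and for the others the cause was not tested. Of 9 list calls, 7 were kept under quantile normalization, 6 with probe sets averaged, 8 with the offset, 8 with signals set to background, and 9 with deposited values or the other alignment, which move every gene of a sample alike and could not change them.

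Erythroid genes in replicate 1 lost their call at 0.75 (quantile), 0.60 (probe sets averaged) and without replicate 3, with 0.50 to 1.07 over samples left out. Hindgut in replicate 3 lost it at -1.93 (probe sets averaged), -1.74 (offset), -1.20 (set to background) and without replicate 2 (range -3.85 to -2.93). Ribosomal proteins in replicate 2 lost it at 0.0732 (quantile), 0.12 (probe sets averaged) and 0.0837 (without replicate 1). They stood at -0.000117 without replicate 3, where the call itself was not recorded, and turned negative at -0.23 under the added alignment. Tubercle mesenchyme transcription factors in replicate 2 turned negative at -0.0902 under that alignment, stood higher at 0.53 (quantile), 0.63 (probe sets averaged) and 0.41 (deposited values), and lay between -0.00833 without replicate 3 and 0.327 without replicate 1. Those turns under the alignment follow from its constant, and the calls against random lists were kept. Leaving out a sample from the landmark contrast leaves 1 against 1, which gives values and no count. No paired analysis was possible because the series has 1 group. Signals near background, with medians of 205 to 334 against backgrounds of 135.8 to 253.1, limit what can be said of dim genes.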

Other observations

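Of the tests in this part, those of mixed female RNA, of circulating blood and of the array's signal scale, the comparisons with 1 sample alone and those with signals set to background, were chosen only after the results were seen, and the lists of imprinted, X-linked and additional tissue genes were written after the first list shifts were known but before their own values were. Genes named from those lists were chosen after their values were seen. Imprinted genes, which are expressed from 1 parental copy and govern embryonic growth, were above background in 3 of 3 samples for most of those measured. The growth factor Igf2 had a signal of 21474 ± 3275 (SD, n = 3), the zinc finger gene Peg3 55596 ± 6879, the growth inhibitor Grb10 54916 ± 3130.3, Plagl1 45232 ± 7412 and the non-coding RNA Meg3 17092 ± 492. The cell cycle inhibitor Cdkn1c read 9168, 19703 and 10145 in replicates 1, 2 and 3. Over 11 imprinted genes the median log2 difference from the other samples was 0.09, -0.01 and 0.17, inside the limits of random lists, and Peg10 was above background in 1 sample alone.

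Genes of erythroid precursors, a list apart from the red cell list of the report, differed between samples too. In replicate 1, 13 of 13 were higher, by a median of 2.56, and in replicate 3, the library of doubtful sex label, 0 of 13, at -1.79. Against replicate 2 alone these medians were 2.15 and -0.99, and with signals below background set to background 2.23 and -1.44. The erythroid regulator Klf1 had signals of 3189, 843 and 292, Hemgn 12860.2, 2141 and 981 and the blood group gene Rhd 3393, 427 and 429 in replicates 1, 2 and 3. An additional list of skeletal muscle genes stood at 1.62 in replicate 1 (9 of 11 higher) and -1.66 in replicate 3, with the cardiac and slow muscle myosin Myh7 at 1554, 384 and 145 and the myosin light chain Myl1 at 1183, 368 and 18.8. Against replicate 2 alone these were 1.09, inside the limits at percentile 99.6, and -1.13, and with signals below background set to background 1.26 and -0.64. Medians in replicate 2 were -0.46 for erythroid precursors and 0.39 for skeletal muscle.

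In replicate 3, the library of doubtful sex label, Xist read 61883 and 3 of 3 Y-linked genes lay below background. Male tissue carrying some female RNA is argued against, because the background of that sample bounds Eif2s3y at 4.86% of its mean signal in replicates 1 and 2, whereas a minor admixture would have left most of it. Tissue of a female embryo under a male label remains open as a hypothesis and is consistent with 4 X-linked genes known to escape inactivation, Kdm6a, Kdm5c, Eif2s3x and Ddx3x, of which 4 of 4 were higher there, by a median log2 difference of 0.54 (percentile 99.4 of random lists, inside the limits used for list calls). That median was 0.80 against replicate 2 alone and 0.2496 against replicate 1 alone (percentile 97.7), just under the 0.25 asked of the full comparison, so its size rests largely on replicate 2, and X-linked genes subject to inactivation had a median of -0.06. A change of label at any step before deposit gives the same values, and the labels hold no further sign of sex.

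Liver transcripts were bright in replicate 1 and dim in replicate 3, the library of doubtful sex label. Alb read 42766, 9061 and 1399.9 and Afp 52165, 40064 and 7049 in replicates 1, 2 and 3. Hbb-y, Hbb-bh1 and Hba-x gave no sign of more circulating blood with embryonic globins in replicate 1 (-0.30, -0.55 and 0.60 there, median -0.30). They cannot exclude more blood with other globins, since Hba-a1 was above background in no sample. Hbb-y also left little room for a rise, at 59853 against a highest signal of 81456 in replicate 1. Less blood with embryonic globins in replicate 3 stays open (0.13, -1.09 and -1.01, median -1.01). The array's signal scale is argued against by the spikes added after amplification, of which the highest stood at -0.12 in replicate 1 while the liver list stood at 3.74. Liver tissue or its RNA in the dissected samples remains open as a hypothesis and is consistent with an additional liver list, 14 of 14 genes of which were higher in replicate 1, by a median of 3.04 (2.35 against replicate 2 alone, and 2.59 with signals below background set to background), with Fgg at 5315, 1360.0 and 267 and Rbp4 at 4924, 1207 and 367. The fetal liver also makes red cells, which may bear on the erythroid lists, but not on the skeletal muscle genes. Whether dissection by reporter fluorescence would exclude liver tissue was not tested. Of the 7 liver genes in the first list 3 were above background in 3 of 3 samples, so expression in the tubercle itself, which was not tested, stays open as well.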
